A study of Rattus norvegicus with 12 samples.

How the data were processed

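The series holds 12 libraries of stranded polyadenylated RNA, read as 50 nt single ends, from cultured rat hippocampal neurons, with 3 libraries in each of 4 groups: control or Grin3a knockdown, each in TTX or 6 h after its withdrawal. Per the labels' protocols, neurons came from embryos at embryonic day 18.5, were infected on day 1 in vitro, received 1 µM TTX on day 5 and were collected on day 7. The labels call the libraries of a group biological replicates, but nothing says whether each came from a separate culture preparation, so p values measure the spread between these samples. The number of reads per library is unknown, which leaves the counting error of each value unknown.

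Per the submitters' processing notes, reads went through Trimmomatic, TopHat2, Cufflinks and Cuffdiff with genome build rn5; versions, roles and the annotation are not given. Library and group values are the authors' FPKM, per the sheet name and the file headers, and how libraries were scaled to each other is not stated. The authors' fold changes are deposited as log2 of the ratio of the group FPKM values. The authors' q-value, a p-value adjusted by Cuffdiff, is deposited for each comparison, and genes below 0.05 are marked as significant. Coordinates are those of the deposited table. The deposited table holds 10730 genes, of which 18 carried symbols turned into dates by a spreadsheet; 17 were resolved. The lowest value of Ctrl_TTX replicate 1 is 1.00 FPKM, whereas the other libraries reach 0 or 0.0436 FPKM, so the genes appear to have been selected on that library. One gene was left out because the mean of its library values differed from the authors' group value by more than 1%. The deposited lists of significant genes equal those marked in the whole table.

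Of the 10729 genes kept, 10689 with an FPKM of at least 1 in at least 3 of 12 libraries were tested and 40 were not. limma 3.58.1 (R 4.3.3; lmFit, contrasts.fit and eBayes with trend = TRUE) was run on log2(FPKM + 1), with 1 coefficient per group and 8 residual degrees of freedom. The 5 contrasts were knockdown in TTX, knockdown after withdrawal, withdrawal in control, withdrawal with knockdown, and the difference between the 2 withdrawal responses. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Log2 changes are differences of mean log2(FPKM + 1), which understate the fold of genes with low values. Grin3a was also tested by an exact permutation of log2(FPKM + 1), with the difference of group means, whose smallest p with 3 against 3 is 0.1. The 26 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within each contrast. fry tests whether a list moves one way on balance and does not compare it with other genes. Every list called by camera lost its call with an estimated correlation. The median, the mean and the test of a list differed in sign only for lists that did not pass, such as heat shock genes and microglia markers with knockdown in TTX and MEF2-linked genes with knockdown after withdrawal. List members without a value in the table, among them Npas4, Nr4a1 and Mef2c, are not analysed here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

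The tests, contrasts, filter, lists, rule for named genes and first set of alternatives were fixed before the data were examined. The rule took Grin3a and the other tested NMDA receptor subunits in both knockdown comparisons. For each contrast it took the 10 genes with the largest change in each direction among those past the threshold, with a group mean of at least 2 FPKM and groups that do not overlap. For the difference between the responses it took the 5 genes with the smallest p. It added up to 4 called members per list, by size of change, and always Fos, Npas4, Arc, Bdnf, Nr4a1, Mef2c and Homer1. Unnamed loci, microRNAs, small nucleolar RNAs and duplicated symbols were passed over. Genes taken from the authors' calls in the knockdown comparisons, single members that passed only within their list, and the antioxidant, ribosomal protein and most strongly lowered genes of the closing section were chosen after their values were seen.

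Whether replicate numbers pair the libraries was checked as the correlation, across genes, of the deviations of same-numbered libraries from their group means. In TTX, control and knockdown libraries correlated at 0.617, 0.436 and 0.667, so the numbers appear to pair these samples. This is read from the data and not from the labels, and so few pairs cannot exclude a match by chance. In the other comparisons at least 1 pair did not exceed 0.1.

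The alternatives fixed in advance were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, rescaling by median ratios, quantile normalization, a robust variance model, the replicate number as a block over 12 libraries, only the 6 libraries compared, and leaving out each library or each replicate number. Added after the data were seen were the replicate block within each treatment, leaving out both outlying control libraries (Ctrl_TTX replicate 1 and the library labelled Ctrl_TTXwd replicate 3), microglia and astrocyte marker means as covariates, library weights estimated gene by gene, and a correction of each library for a smooth trend of its deviations with log10 locus span (loess). Both of these libraries had the lowest mean Spearman correlation with their own group, 0.905 and 0.908. Results for some single genes are not reported here.

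The test was tested on simulated data with 10689 genes, 200 of them changed by 1.5-, 2- or 4-fold. With independent noise it recovered 5.97%, 50.7% and 95.5% of these for knockdown in TTX (8 false calls), 7.46%, 40.3% and 86.4% for withdrawal in control (5), 8.96%, 37.3% and 86.4% for knockdown after withdrawal (5) and 10.4%, 55.2% and 90.9% for withdrawal with knockdown (2). With shuffled residuals of the real libraries it recovered 0%, 31.3% and 86.4% (0 false calls), 13.4%, 44.8% and 87.9% (0), 2.99%, 37.3% and 84.8% (0), and 25.4%, 62.7% and 90.9% (31). All comparisons used the same gene means and residual spread, each with a single random draw. Differences between them therefore come from the draw and do not measure the power of each comparison. Grin3a itself, with 33.6% of its control level left in TTX, was not called by limma in either condition.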

Results

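RNA was measured in 12 libraries of hippocampal neurons taken from rat embryos of both sexes and grown for 7 days. One day after plating, the neurons received a lentivirus with either an empty vector (control) or a short hairpin RNA against Grin3a (knockdown). Grin3a encodes GluN3A, an NMDA-type glutamate receptor subunit. From day 5, all cultures were held for 48 h in tetrodotoxin (TTX), a sodium channel blocker that silences action potentials. They were collected in TTX (groups Ctrl_TTX and KD_TTX) or 6 h after its withdrawal (Ctrl_TTXwd and KD_TTXwd), with 3 libraries per group. The series asks whether GluN3A regulates the transcription that returning activity induces. Levels are the authors' FPKM, and their sum ran from 428158 to 517743 per library over the 10729 genes kept. The number of reads behind each value is unknown.

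Grin3a (chromosome 5, 69420057 to 69564696) stood at 18.6, 18.2 and 23.0 FPKM in the Ctrl_TTX libraries and at 9.30, 6.01 and 4.77 FPKM in KD_TTX. The means were 19.9 ± 2.66 and 6.69 ± 2.34 FPKM (SD, n = 3), so 33.6% of the control level was left. The log2 difference was -1.48, every knockdown library lay below every control library, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. The limma adjusted p over all 10689 genes was 0.936. After withdrawal, Grin3a stood at 13.8, 19.8 and 4.88 FPKM in Ctrl_TTXwd and at 5.22, 3.32 and 2.502 FPKM in KD_TTXwd. The means were 12.8 ± 7.51 and 3.68 ± 1.39 FPKM, with 28.7% left, an exact two-sided permutation p of 0.2 and a limma adjusted p of 0.301. The library labelled Ctrl_TTXwd replicate 3, at 4.88 FPKM, lay within the range of the knockdown libraries; without it, the control mean was 16.8 FPKM and 21.9% was left. Every comparison below that uses Ctrl_TTXwd includes this library as labelled. The authors' deposited table gives log2 differences of -1.58 in TTX and -1.80 after withdrawal, both at q = 0.00102.

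By limma, none of the 5 other NMDA receptor subunits tested passed the threshold over all genes with knockdown in either condition. The authors' deposited table calls Grin2a after withdrawal (log2 difference 1.23, q = 0.00102) and none of the other 4 in either condition. In TTX, Grin2b, the juvenile GluN2B subunit, stood at 31.8 ± 2.37 FPKM with knockdown and 40.8 ± 4.13 FPKM in control. Grin1, the obligatory subunit, stood at 52.97 ± 9.93 against 61.5 ± 13.9 FPKM, and Grin2a at 5.99 ± 1.39 against 7.59 ± 0.81 FPKM (SD, n = 3). Grin2c stood at 1.83 ± 0.84 against 1.07 ± 0.07 and Grin2d at 5.20 ± 1.40 against 3.33 ± 0.60 FPKM (limma adjusted p for all 5 from 0.936 to 0.947). After withdrawal, Grin2a, the mature GluN2A subunit, stood at 5.56 ± 0.98 FPKM with knockdown and 2.37 ± 0.91 FPKM in control (log2 difference 0.99, limma adjusted p = 0.263). Adjusted over the list alone, Grin3a passed in both conditions and Grin2a passed after withdrawal. Grin1 stood at 37.7 ± 2.02 against 45.8 ± 17.7 FPKM, and Grin2b at 14.8 ± 2.87 against 10.6 ± 4.57 FPKM. Grin2c stood at 0.71 ± 0.13 against 0.67 ± 0.38 and Grin2d at 1.95 ± 0.60 against 1.96 ± 0.81 FPKM (limma adjusted p from 0.471 to 0.983).

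**Figure D1:**
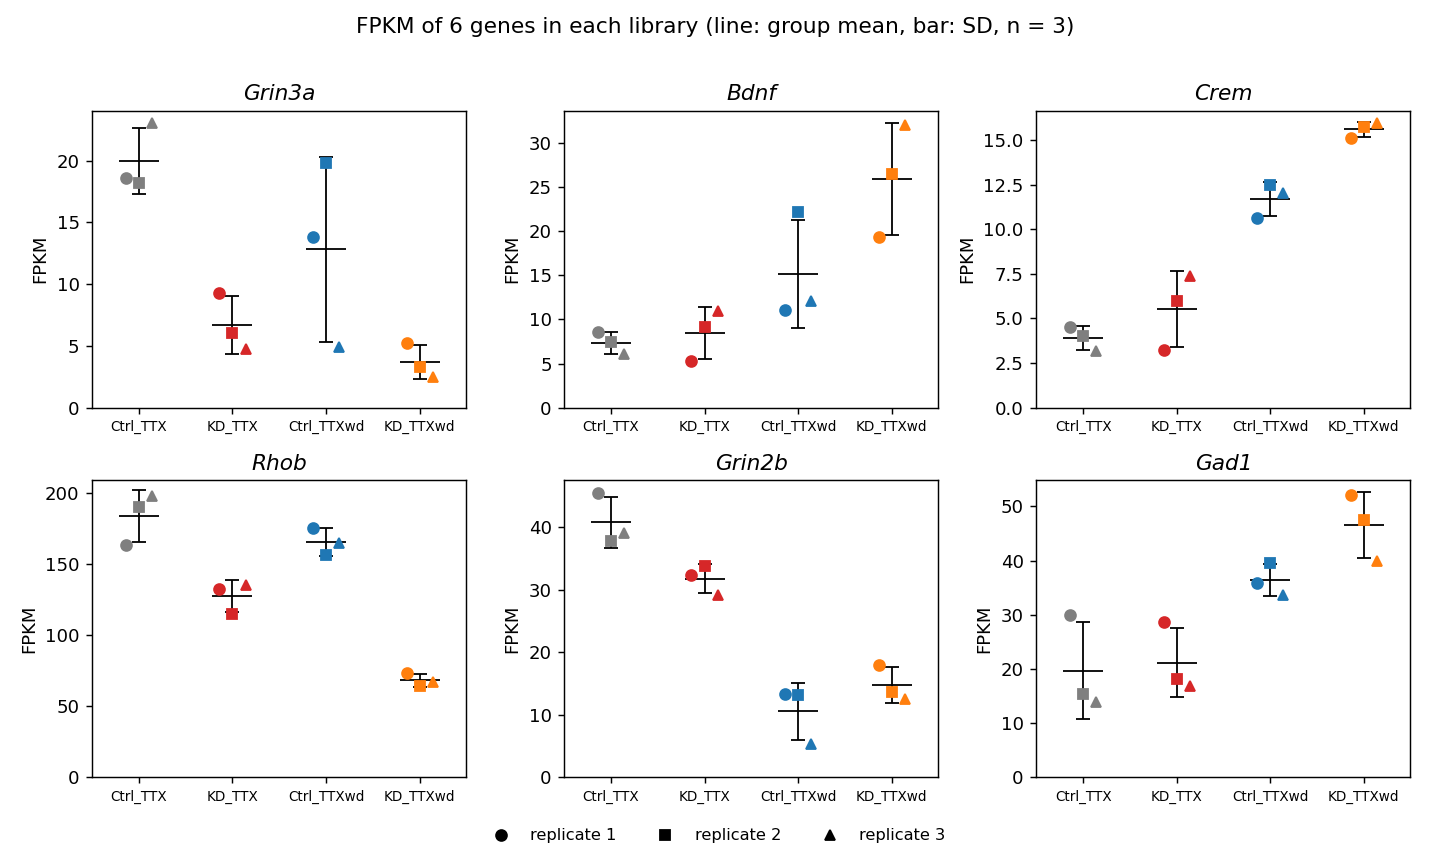
FPKM of Grin3a, Bdnf, Crem, Rhob, Grin2b and Gad1 in each library, by group (Ctrl_TTX, KD_TTX, Ctrl_TTXwd, KD_TTXwd). Points are libraries, and bars give the mean ± SD of the 3 libraries of a group.

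In control neurons, 6 h without TTX left 707 genes higher and 1189 lower than in TTX, 218 and 565 of them by at least 2-fold. Ribosomal protein transcripts were among the largest rises: Rpl17 rose from 9.33 ± 2.28 to 112 ± 18.8 FPKM, Rpl30 from 14.98 ± 5.82 to 112 ± 12.3 and Rps15a from 8.62 ± 5.65 to 51.8 ± 12.0 FPKM (SD, n = 3). The quinone reductase Nqo1 rose from 25.97 ± 0.27 to 233 ± 163 FPKM and sulfiredoxin Srxn1 from 6.97 ± 0.73 to 39.8 ± 10.3 FPKM. The glutathione transferase Gsta1 rose from 9.24 ± 3.35 to 54.2 ± 38.0 and the metallothionein Mt2A from 29.8 ± 13.7 to 147 ± 66.3 FPKM. Ddit4l, an inhibitor of mTOR signalling, rose from 6.75 ± 2.34 to 53.9 ± 15.03 FPKM, Tmem256 from 6.64 ± 1.495 to 47.4 ± 13.4 and the calcium-binding S100a11 from 8.90 ± 2.65 to 73.7 ± 68.1 FPKM. In the other direction, Rps2, also a ribosomal protein gene, fell from 238 ± 176 to 0.84 ± 0.57 FPKM. Basp1, a growth cone membrane protein, fell from 1446 ± 261 to 117 ± 71.4 FPKM.

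The remaining genes with the largest falls in control neurons were Tmem158 (31.6 ± 17.4 to 0.92 ± 1.28 FPKM), the dynein-associated Nudc (17.4 ± 3.08 to 0.66 ± 1.04) and the CDK5 activator Cdk5r2 (29.5 ± 12.7 to 2.22 ± 1.75). They also held the orphan receptor Gpr139 (50.9 ± 37.5 to 4.05 ± 1.00 FPKM), Prr7 (42.8 ± 18.6 to 4.88 ± 4.29), the transcription factor Sox12 (47.6 ± 17.5 to 6.00 ± 4.37), Rprml (67.2 ± 42.6 to 8.02 ± 5.56) and C1qtnf4 (30.2 ± 16.6 to 4.09 ± 4.16). limma adjusted p of these 20 genes ran from 0.00018 to 0.0295. Reads of ribosomal protein genes can be shared with pseudogenes, and this could not be checked without the genome. The authors' deposited table calls 969 genes higher and 1489 lower in this comparison, and 1463 of these were called here in the same direction.

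The share of higher calls among the 1896 in control neurons depended on scaling: 37.3% here, 46.2% (918 higher and 1068 lower) with median ratios and 47.1% (916 and 1029) after quantile normalization. Selection of genes may also lower this share. The table appears to hold only genes expressed in Ctrl_TTX replicate 1, so genes silent there that rise after withdrawal would be missing. The calls rested on the spread estimated from all 12 libraries: with only the 6 libraries compared, 1 gene was higher and 0 were lower. Higher and lower genes numbered 382 and 785 without Ctrl_TTX replicate 2, 424 and 748 without Ctrl_TTX replicate 3, and 329 and 627 without the library labelled Ctrl_TTXwd replicate 3. The higher genes alone numbered 454 without KD_TTX replicate 2 and 428 without Ctrl_TTXwd replicate 1. With a replicate number left out of all 4 groups, 0 genes were called without replicate 2, and 4 higher and 0 lower without replicate 3.

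Among genes that neuronal activity is known to induce, few of the transcription factors tested passed in control neurons: 1 of 19 was higher and 2 were lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.548). Crem, a cAMP-responsive factor, rose from 3.91 ± 0.67 to 11.7 ± 0.97 FPKM. Nr4a3 fell from 101 ± 17.9 to 38.0 ± 14.6 FPKM and Egr3 from 6.61 ± 0.44 to 2.05 ± 1.08 FPKM. Fos stood at 17.0 ± 6.81 FPKM in TTX and 18.46 ± 4.23 FPKM after withdrawal (limma adjusted p = 0.811). Of 26 activity-induced effectors, 5 were higher, 0 were lower and 21 did not pass (8 and 0 adjusted over the list alone; camera adjusted p = 0.0473). They were the peptide precursor Tac1 (8.42 ± 1.91 to 31.0 ± 10.9 FPKM), the G protein regulator Rgs2 (20.4 ± 3.27 to 62.9 ± 25.7) and Vgf (10.6 ± 4.40 to 28.4 ± 10.2), with Scg2 (121 ± 74.8 to 222 ± 25.3 FPKM) and Sorcs3 (log2 change 0.98). Sorcs3 was named after its value was seen. Arc stood at 1.25 ± 0.18 and 3.33 ± 1.35 FPKM (adjusted p = 0.0556 by limma), Bdnf at 7.36 ± 1.25 and 15.2 ± 6.14 FPKM (0.0611) and Homer1 at 35.6 ± 0.61 and 26.3 ± 3.28 FPKM (0.0974). The authors' deposited table calls Arc (log2 difference 1.42, q = 0.00387) and Bdnf (1.04, q = 0.00184) higher after withdrawal, but not Fos or Homer1. The fixed genes Npas4, Nr4a1 and Mef2c are not analysed here. The genes of the table appear to have been selected at 1 FPKM in a TTX library, so factors silent in TTX would not be counted; of 25 fixed factors, 19 were tested. Of 15 MEF2 factors and MEF2-linked genes, 0 were higher and 3 were lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.0473). Mef2d fell from 38.5 ± 18.0 to 13.3 ± 3.59 FPKM, Mef2a from 45.6 ± 16.3 to 17.3 ± 1.93 and Hdac4, a repressor of MEF2, from 16.9 ± 2.56 to 9.21 ± 2.72 FPKM. Without the library labelled Ctrl_TTXwd replicate 3, the MEF2 list had a camera adjusted p of 0.213, and without Ctrl_TTX replicate 1 one of 0.146. For the effectors and the MEF2 list, adjusted p = 0.506 with an estimated correlation. The effectors had a camera adjusted p of 0.0567 with median ratios and 0.0602 after quantile normalization, and the MEF2 list one of 0.0536 after the latter.

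Of the lists of glutamatergic neurons and synapses, 6 passed by camera for withdrawal in control neurons, each with part of its members lower; with an estimated correlation none passed (adjusted p = 0.506 for each). Of 24 postsynaptic scaffolds and adhesion molecules, 14 were lower and 0 higher (16 and 0 adjusted over the list alone; camera adjusted p = 2.97e-06). Shank1 fell from 88.3 ± 4.21 to 16.6 ± 9.48 FPKM, Dlgap3 from 29.5 ± 11.9 to 5.31 ± 3.17 FPKM. Nrxn2 fell from 107 ± 35.4 to 35.0 ± 18.48 and Nlgn2 from 116 ± 19.4 to 38.4 ± 13.2 FPKM. Of 14 glutamatergic neuron markers, 9 were lower and 0 higher (11 and 0 adjusted over the list alone; camera adjusted p = 1.26e-05). Among them, the transcription factor Neurod2 fell from 57.8 ± 34.7 to 11.6 ± 4.63 FPKM and Zbtb20 from 48.8 ± 5.53 to 13.6 ± 4.16 FPKM. Of 6 NMDA receptor subunits, 2 were lower and 0 higher (2 and 0 adjusted over the list alone; camera adjusted p = 0.0105). Grin2b fell from 40.8 ± 4.13 to 10.6 ± 4.57 FPKM and Grin2a from 7.59 ± 0.81 to 2.37 ± 0.91 FPKM. Of 15 AMPA and kainate receptor subunits and their auxiliary proteins, 3 were lower and 0 higher (4 and 1 adjusted over the list alone; camera adjusted p = 0.0105). Cacng2, which encodes stargazin, fell from 41.7 ± 18.1 to 8.37 ± 1.01 FPKM, Gria2 from 165 ± 53.3 to 97.5 ± 10.996 and Cacng4 from 120 ± 16.4 to 75.4 ± 13.4 FPKM. Grm4, 1 of 6 metabotropic glutamate receptors, fell (5 lower and 0 higher adjusted over the list alone; camera adjusted p = 0.0099). Of 21 vesicle and release genes, 7 were lower and 0 higher (12 and 1 adjusted over the list alone; camera adjusted p = 0.00067). Complexin Cplx2 fell from 229 ± 85.0 to 62.7 ± 21.9 FPKM and synapsin Syn1 from 200 ± 126 to 70.6 ± 29.0 FPKM.

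Among ion channel lists in control neurons, 2 passed by camera. Of 24 potassium and HCN channels, 8 were lower and 0 higher (9 and 0 adjusted over the list alone; camera adjusted p = 0.00067). Of 7 voltage-gated sodium channels, Scn8a fell from 16.2 ± 2.25 to 7.04 ± 1.44 FPKM (4 lower adjusted over the list alone; camera adjusted p = 0.0473). Of 14 interferon-stimulated genes, Isg15 rose from 2.16 ± 0.97 to 6.27 ± 0.51 FPKM (1 adjusted over the list alone; camera adjusted p = 0.0105). Of 15 p53 response genes, Tp53inp1 rose from 17.3 ± 0.25 to 34.0 ± 6.88 FPKM and Sesn1 from 11.4 ± 0.57 to 21.4 ± 5.10 FPKM (2 adjusted over the list alone; camera adjusted p = 0.0497). For each of these 4 lists, adjusted p = 0.506 with an estimated correlation. Without the library labelled Ctrl_TTXwd replicate 3, the AMPA and kainate, sodium channel, interferon and p53 lists had camera adjusted p values of 0.109, 0.196, 0.076 and 0.109. Without Ctrl_TTX replicate 1, the sodium channel and p53 lists had 0.101 and 0.198, and the p53 list had 0.0545 with median ratios. fry called 11 of the 12 lists, with p53 at an adjusted p of 0.114. Without the library labelled Ctrl_TTXwd replicate 3, 7 lists passed in place of 12. In that Ctrl_TTXwd library the glutamatergic marker mean was 4.01 log2 units against 4.98 and 5.14 in the other Ctrl_TTXwd libraries, and the microglia marker mean was 6.46 against 5.08 and 2.83.

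The change with withdrawal in control neurons went with the span of a gene's locus, with longer loci lower (Spearman's rho = -0.214 over the tested genes). After each library was corrected for this trend, an alternative chosen after the data were seen, 7 of the 12 lists passed. The camera adjusted p was then 5.51e-05 for scaffolds and adhesion molecules, 9.12e-06 for glutamatergic neuron markers, 0.000538 for vesicle and release genes, 0.00092 for potassium and HCN channels, 0.0169 for NMDA subunits and for interferon-stimulated genes and 0.0182 for metabotropic receptors. The effectors, the MEF2 list and the AMPA and kainate, sodium channel and p53 lists had 0.0819, 0.055, 0.101, 0.0762 and 0.14. After this correction 8 named genes no longer passed, with limma adjusted p values from 0.0591 to 0.116, though each kept its direction. Their log2 changes before and after were 1.03 and 0.93 for Scg2, -0.84 and -0.56 for Hdac4, -0.71 and -0.48 for Gria2 and -0.66 and -0.51 for Cacng4. They were -0.78 and -0.58 for Spred2, 0.49 and 0.40 for Dusp6, -1.10 and -0.92 for Bcas1 and -1.02 and -0.80 for Mbp. Bdnf passed (0.90 and 1.03, 0.0437).

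Other groups did not pass camera in control neurons. Of 15 GABAergic neuron markers, 1 was higher and 2 were lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.343). Gad1, the GABA-synthesising enzyme, rose from 19.7 ± 8.91 to 36.4 ± 2.97 FPKM. The transcription factors Dlx2 (5.94 ± 1.71 to 1.38 ± 0.66 FPKM) and Lhx6 (6.47 ± 2.41 to 2.53 ± 1.06) fell. Of 11 GABA-A receptor subunits, 3 were lower adjusted over the list alone (camera adjusted p = 0.101). Of 12 neuropeptides and granins, 3 were higher and 1 was lower (3 and 4 adjusted over the list alone; 0.472), Chgb falling from 142 ± 52.3 to 58.3 ± 28.6 FPKM. Of 12 MAP kinase feedback genes, Dusp6 rose and Spred2 fell (3 and 1 adjusted over the list alone; 0.275). Of 15 progenitor and cell cycle genes, Cdk1 and Pcna rose and Hes5 fell (2 and 1 adjusted over the list alone; 0.301). Of 7 oligodendrocyte lineage markers, Bcas1 and Mbp, a myelin protein, fell (3 lower adjusted over the list alone; camera 0.0804, fry adjusted p = 0.0473). Of 16 genes of the unfolded protein and integrated stress response, Manf fell from 134 ± 17.3 to 51.7 ± 7.12 FPKM (1 adjusted over the list alone; 0.682). Of 7 heat shock genes Hsp90aa1 fell (1 adjusted over the list alone; 0.682). Of 15 glycolysis and hypoxia genes, Pkm and Hk1 fell (2 adjusted over the list alone; 0.375). By limma, 0 of 12 astrocyte markers, 0 of 14 microglia markers, 0 of 10 vascular and fibroblast markers and 0 of 19 cholesterol synthesis genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.69, 0.275, 0.376 and 0.139). Of the calls named for control neurons, those of Dusp6 (7 of 28), Cacng4 (10), Scg2, Spred2 and Gria2 (11 each), Cdk1 (13) and Bcas1 (13 of 27) were kept in fewer than 14 of the other settings.

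**Figure D2:**
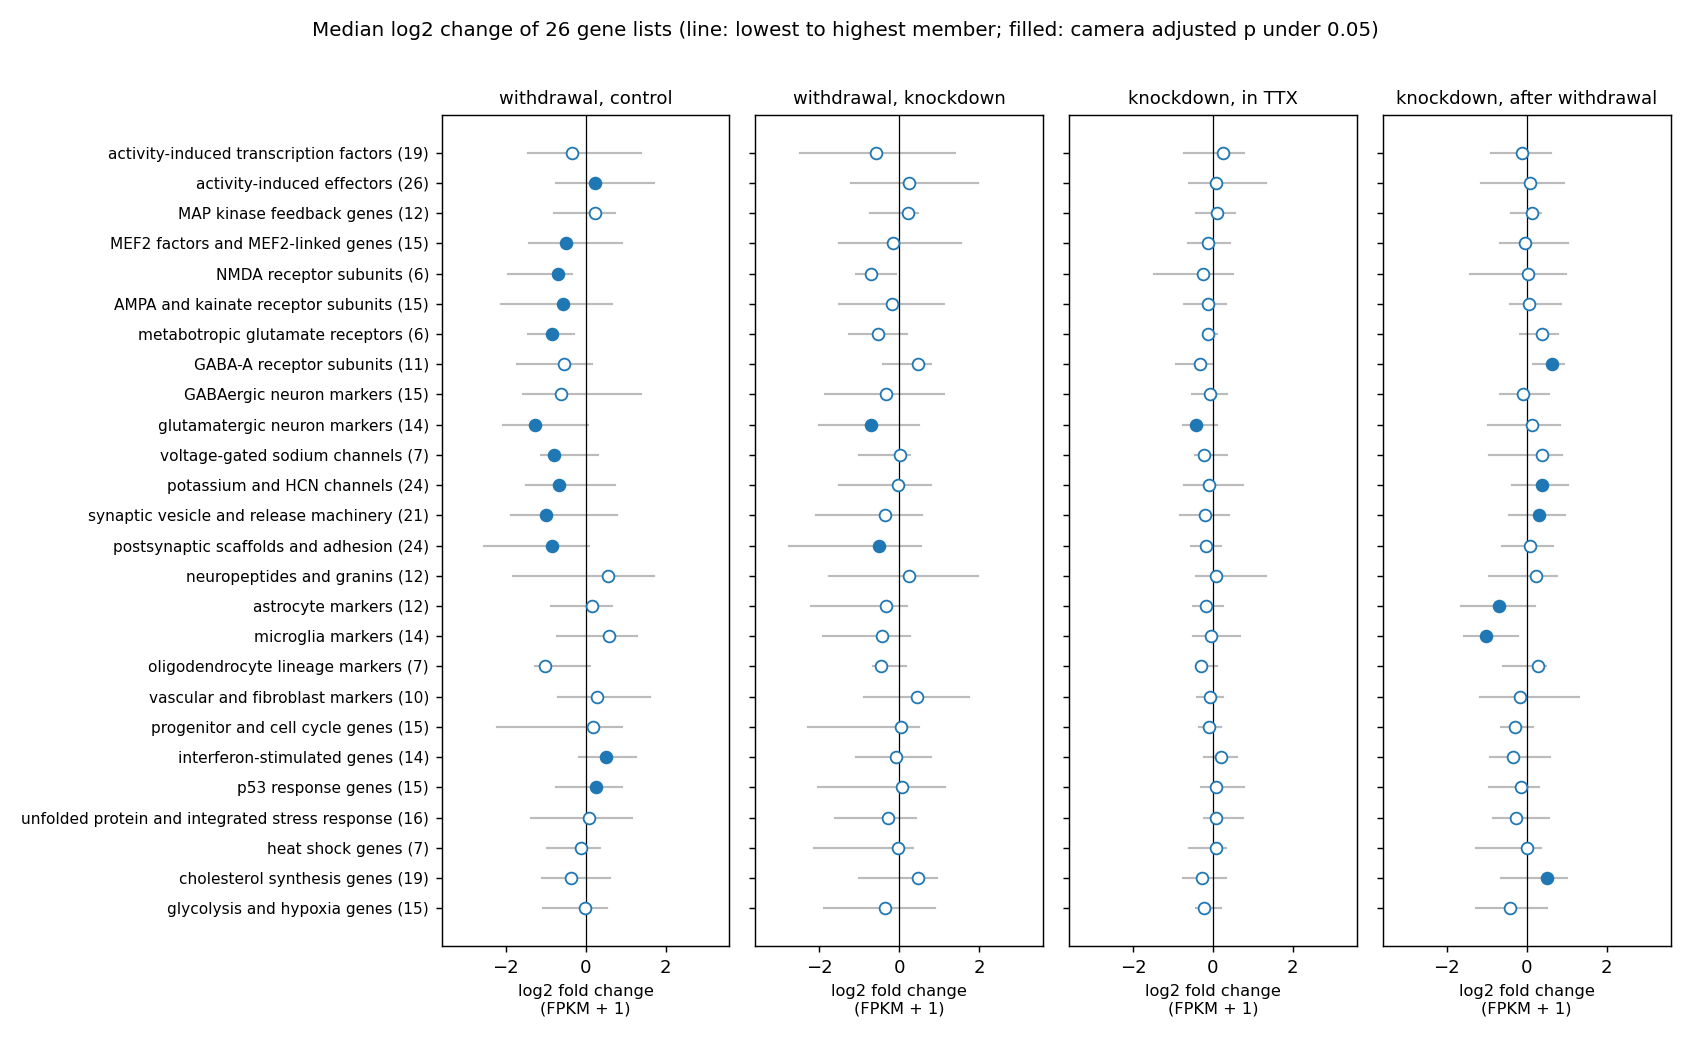
Median log2 change of the tested members of each of the 26 gene lists in the comparisons of knockdown with control and of withdrawal with TTX. Lines run from the lowest to the highest member, and filled points mark a camera adjusted p under 0.05.

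In knockdown neurons, withdrawal left 529 genes higher and 985 lower, 102 and 616 of them by at least 2-fold. Rpl17 rose from 12.2 ± 3.64 to 147 ± 35.6 FPKM (SD, n = 3) and Rpl30 from 33.9 ± 21.2 to 132 ± 23.3 FPKM. Mlf1, a myeloid leukemia factor, rose from 3.22 ± 0.51 to 23.6 ± 1.82 FPKM and the protease Tll1 from 2.32 ± 0.52 to 13.3 ± 3.00 FPKM. The cation channel Trpc6 rose from 1.29 ± 0.24 to 8.46 ± 0.59 FPKM and Crhbp, which binds corticotropin-releasing hormone, from 1.13 ± 0.40 to 7.38 ± 2.04 FPKM. Tac1 rose from 13.2 ± 5.85 to 51.3 ± 9.77 FPKM, Nqo1 from 45.4 ± 9.99 to 176 ± 89.7 and Tmem256 from 11.2 ± 6.47 to 42.8 ± 7.54 FPKM. Rps2 fell from 229 ± 97.3 to 0.29 ± 0.13 FPKM, Basp1 from 1042 ± 183 to 71.1 ± 27.4 and Tmem158 from 24.8 ± 6.88 to 0.12 ± 0.10 FPKM. Prr7 fell from 41.6 ± 7.40 to 1.46 ± 0.45 and Nudc from 17.4 ± 3.58 to 0.06 ± 0.08 FPKM. Scand1, Sox12, C1qtnf4 and the transcription factors Cebpd and Bmyc completed the largest falls, with log2 changes of -3.97, -3.94, -3.70, -3.56 and -3.56. limma adjusted p of these genes ran from 0.000162 to 0.0186.

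In knockdown neurons, 1 of 19 activity-induced transcription factors was higher and 6 were lower (2 and 9 adjusted over the list alone; camera adjusted p = 0.0935, fry adjusted p = 0.0433). Crem rose from 5.53 ± 2.13 to 15.6 ± 0.41 FPKM, while the immediate-early genes Junb (21.99 ± 3.29 to 3.44 ± 2.03 FPKM), Jun (104 ± 6.96 to 36.1 ± 2.37) and Ier2 (30.3 ± 6.05 to 9.79 ± 2.42) fell. Of 26 effectors, 6 were higher and 1 was lower (7 and 2 adjusted over the list alone; camera 0.074, fry 0.0275). Bdnf, a neurotrophin, rose from 8.45 ± 2.92 to 25.97 ± 6.37 FPKM, Rgs2 from 13.04 ± 1.95 to 43.8 ± 7.99 and Sorcs3 from 3.08 ± 0.34 to 10.8 ± 1.43 FPKM. Fos stood at 22.8 ± 8.38 and 22.3 ± 10.1 FPKM, Arc at 2.18 ± 1.32 and 1.72 ± 0.51 and Homer1 at 30.5 ± 5.81 and 37.5 ± 4.41 FPKM (limma adjusted p = 0.904, 0.75 and 0.251). Of 15 MEF2-linked genes, 2 were higher and 5 lower (2 and 6 adjusted over the list alone; 0.375). The secreted synaptic protein Lgi1 rose from 25.0 ± 2.295 to 49.5 ± 4.10 FPKM and Mef2d fell from 28.5 ± 9.90 to 11.4 ± 0.43 FPKM. Scaffolds and adhesion molecules passed the list test, with 10 of 24 lower and 0 higher (11 and 0 adjusted over the list alone; camera adjusted p = 0.00298). Dlgap3 fell from 27.5 ± 0.62 to 3.37 ± 1.39 FPKM and Shank1 from 74.5 ± 16.2 to 15.7 ± 4.85 FPKM. Glutamatergic neuron markers passed with 3 of 14 lower and 0 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.0451; 0.12 without Ctrl_TTX replicate 1), among them Nrgn and Neurod2. For both lists, adjusted p = 0.84 with an estimated correlation; by fry they had 0.0952 and 0.157. In place of 2 lists, 4 passed without KD_TTXwd replicate 1, and 1 passed without Ctrl_TTX replicate 1, Ctrl_TTX replicate 2 or KD_TTXwd replicate 3.

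The other lists did not pass in knockdown neurons, though single members changed. Grin2b fell from 31.8 ± 2.37 to 14.8 ± 2.87 FPKM and Grin2d from 5.20 ± 1.40 to 1.95 ± 0.60 FPKM (NMDA subunits, camera adjusted p = 0.074). Cacng2, Cacng8 and the kainate receptor subunit Grik5 fell while Cacng3 rose from 10.4 ± 1.18 to 24.0 ± 2.18 FPKM (0.234). Gad1 rose from 21.2 ± 6.44 to 46.5 ± 6.15 FPKM while Slc32a1, the vesicular GABA transporter, fell from 13.1 ± 1.10 to 3.69 ± 1.83 and Dlx2 from 4.98 ± 3.54 to 0.47 ± 0.21 FPKM (GABAergic neuron markers, 0.318). Id3 (astrocyte list, 0.261) fell from 37.1 ± 17.9 to 7.12 ± 3.38 FPKM and Gdf15 (p53 response, 0.426) from 4.84 ± 1.87 to 0.40 ± 0.24 FPKM. Hspb1 (heat shock, 0.846) fell from 31.8 ± 12.3 to 6.77 ± 3.84 FPKM, Manf (stress response, 0.318) from 120 ± 27.0 to 38.3 ± 6.29 and the glycolytic enzyme Pfkl (0.261) from 67.5 ± 5.54 to 18.0 ± 4.79 FPKM. The stromal proteoglycan Dcn (vascular list, 0.361) rose from 9.59 ± 2.29 to 34.5 ± 8.28 FPKM.

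The authors' deposited table calls 580 genes higher and 1463 lower for withdrawal in knockdown neurons, and 1223 of these were called here in the same direction. The share of higher calls among the 1514 depended on scaling: 34.9% here, but 50.4% (947 higher and 932 lower) after quantile normalization. Here too, genes silent in Ctrl_TTX replicate 1 that rise after withdrawal would be missing from the table. Higher and lower genes numbered 1025 and 1609 without Ctrl_TTX replicate 1, 207 and 490 without KD_TTX replicate 1 and 104 and 341 without KD_TTX replicate 2. They numbered 75 and 261 without KD_TTXwd replicate 1, 152 and 554 without KD_TTXwd replicate 2, 277 and 616 without KD_TTXwd replicate 3, and 921 and 1601 with only the 6 libraries compared. With a replicate number left out of all 4 groups, they numbered 241 and 604 without replicate 1, 0 and 0 without replicate 2 and 170 and 496 without replicate 3.

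The responses to withdrawal in the 2 genotypes, which share no library, shared many genes: 272 were higher in both, 502 lower in both and 0 called in opposite directions. Independent calls would give 35.0 and 110. The calls are not independent, since both use 1 spread per gene from all 12 libraries, so chance may give more. Opposite calls numbered 3 without Ctrl_TTXwd replicate 2. Among alternatives chosen after the data were seen, they numbered 1 with the replicate block within treatment and 2 without both outlying control libraries. With the marker covariates they numbered 41, and with the library weights 122. Without any single library, the genes higher in both ran from 55 to 430 and those lower in both from 199 to 796. Without replicate 2 in all groups both counts were 0, and without replicate 3 they were 3 and 0. Across the 10689 genes the log2 changes correlated at r = 0.650 (Spearman's rho = 0.586); genes are not independent replicates. Rps2, Basp1, Tmem158, Nudc, Shank1, Dlgap3, Grin2b and Cacng2 fell in both genotypes, and Rpl17, Nqo1, Tac1, Rgs2, Crem and Gad1 rose in both.

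Knockdown of Grin3a in TTX, the comparison in silenced neurons, called no gene: limma gave 0 higher and 0 lower (smallest adjusted p 0.936), with 412 genes at an unadjusted p under 0.05 where chance gives 534. The groups did not overlap in 11.8% of genes, against 10% by chance. The authors' deposited table calls 36 genes higher and 196 lower here. All 231 of them that were tested had the same sign, 89 had an unadjusted p under 0.05 by limma and in 104 the groups did not overlap. Both sets of values come from the same libraries, so these counts are no independent support. The following of the authors' genes were chosen after their values were seen, and all have a limma adjusted p of 0.936. Ddit4l stood at 17.0 ± 3.64 FPKM with knockdown and 6.75 ± 2.34 FPKM in control (SD, n = 3), and Srxn1 at 20.6 ± 9.29 and 6.97 ± 0.73 FPKM. The GTPase Arf4 stood at 785 ± 184 and 443 ± 25.8 FPKM, and Vgf, a neurosecretory protein, at 26.7 ± 7.00 and 10.6 ± 4.40 FPKM. On the lower side, the heat shock factor Hsf2 stood at 42.5 ± 5.44 and 77.7 ± 15.3 FPKM, the protease Adamts18 at 12.3 ± 1.39 and 20.5 ± 0.17 and the kinase Map4k3 at 34.1 ± 3.18 and 58.5 ± 12.2 FPKM. Fos stood at 22.8 ± 8.38 with knockdown and 17.0 ± 6.81 FPKM in control and Arc at 2.18 ± 1.32 and 1.25 ± 0.18 FPKM. Bdnf stood at 8.45 ± 2.92 and 7.36 ± 1.25 and Homer1 at 30.5 ± 5.81 and 35.6 ± 0.61 FPKM (limma adjusted p for the 4 genes from 0.936 to 0.976).

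As a group, glutamatergic neuron markers were lower with knockdown in TTX, with a median log2 difference of -0.42 and 12 of 14 members below 0 (camera adjusted p = 0.00233; adjusted p = 0.868 with an estimated correlation). No single member passed over all genes or adjusted over the list alone. By limma and adjusted over the list alone, Vgf of the neuropeptide list passed, named after its value was seen. The libraries of this comparison deviate together by replicate number, and with that number as a block, GABA-A receptor subunits (camera adjusted p = 0.023), cholesterol synthesis genes (0.023) and activity-induced transcription factors (0.0464) passed too. With an estimated correlation and the block, adjusted p = 0.79 for each of the 3. Without the block their camera adjusted p values were 0.0637, 0.0534 and 0.0637; cholesterol synthesis genes had 0.0198 with median ratios and 0.0493 after quantile normalization. The 11 GABA-A receptor subunits had a median log2 difference of -0.32 and the 19 cholesterol synthesis genes one of -0.28, both lower with knockdown; the 19 activity-induced transcription factors had a median of 0.24. In place of 1 list, 5 passed without Ctrl_TTX replicate 1, 6 without KD_TTX replicate 1, 4 without KD_TTX replicate 3, 3 without any single Ctrl_TTXwd library and 2 without Ctrl_TTX replicate 2 or 3, KD_TTX replicate 2 or KD_TTXwd replicate 2 or 3.

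After withdrawal, limma over the 12 libraries called Rhob lower with knockdown and no other gene. Rhob (chromosome 6, 43472712 to 43474862), a small GTPase of endosomes and the actin skeleton that is also an immediate-early gene, stood at 68.2 ± 4.67 FPKM with knockdown and 166 ± 9.63 FPKM in control (SD, n = 3; log2 difference -1.27, SE 0.14, limma adjusted p = 0.0167). The library labelled Ctrl_TTXwd replicate 3, whose Grin3a was at the knockdown level, had Rhob at 165 FPKM. Rhob was called with this library counted as a control, so its level there follows from the selection and cannot decide the label. limma called 0 genes higher and 1 lower, with 1276 genes at an unadjusted p under 0.05 against 534 by chance and groups that did not overlap in 19.8% of genes against 10% by chance. The Rhob call was kept in 14 of 28 other settings (limma adjusted p over the 28 settings from 0.000808 to 0.881). The 14 that ended it include those without Ctrl_TTX replicate 2, without any single library of Ctrl_TTXwd or KD_TTXwd and without each replicate number. Quantile normalization, the replicate block over 12 libraries and only the 6 libraries compared also ended the call. After each library was corrected for locus span it ended as well, with a log2 difference of -1.03 (limma adjusted p = 0.177). Without Ctrl_TTX replicate 1, 4 genes were lower. Of the alternatives chosen after the data were seen, microglia and astrocyte marker means as covariates called 383 higher and 405 lower, and library weights, whose error rate was not tested, 960 and 1338.

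The authors' deposited table calls 173 genes higher and 641 lower with knockdown after withdrawal. Of the 813 tested, all had the same sign here, 447 had an unadjusted p under 0.05 by limma and in 327 (40.2%) the groups did not overlap. Since the authors' values come from the same libraries, these counts are no independent support. Chosen after their values were seen, the following had limma adjusted p values from 0.173 to 0.263. The orexin receptor Hcrtr2 stood at 4.12 ± 0.66 FPKM with knockdown and 1.24 ± 0.54 FPKM in control (SD, n = 3). The kinase Prkx stood at 36.3 ± 6.04 and 18.2 ± 2.40 FPKM and Prkaa2, a catalytic subunit of AMPK, at 19.6 ± 1.34 and 10.2 ± 1.65 FPKM. The zinc finger factor Hivep2 stood at 44.0 ± 4.55 and 22.9 ± 2.76 FPKM. On the lower side, the nuclear import receptor Ipo9 stood at 24.5 ± 0.92 and 44.2 ± 3.22 FPKM, the disulfide isomerase Txndc5 at 29.5 ± 8.88 and 78.1 ± 26.4 and the glycolytic enzyme Pgam1 at 35.6 ± 9.28 and 105 ± 11.4 FPKM. Bdnf stood at 25.97 ± 6.37 with knockdown and 15.2 ± 6.14 FPKM in control, and Arc at 1.72 ± 0.51 and 3.33 ± 1.35 FPKM. Homer1 stood at 37.5 ± 4.41 and 26.3 ± 3.28 and Fos at 22.3 ± 10.1 and 18.46 ± 4.23 FPKM (limma adjusted p = 0.363, 0.422, 0.328 and 0.868 for the 4 genes in turn). Of these 4, the authors' deposited table calls Bdnf (log2 difference 0.78, q = 0.023). It does not call Arc (-0.95, q = 0.0522), Homer1 or Fos. With the library labelled Ctrl_TTXwd replicate 3 and Ctrl_TTX replicate 1 both left out, an alternative chosen after the data were seen, 124 genes were higher and 403 lower.

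Among the gene lists after withdrawal, all 11 GABA-A receptor subunits lay above control with knockdown (median log2 difference 0.63, camera adjusted p = 0.000901). Potassium and HCN channels (median 0.39, 0.001), vesicle and release genes (0.32, 0.019) and cholesterol synthesis genes (0.50, 0.0403) were higher as groups. Markers of astrocytes (median -0.68, 0.00183) and of microglia (median -1.02, 0.0379, 14 of 14 below 0) were lower. By limma, 0 members of these 6 lists passed over all genes. Adjusted over the list alone, Sv2b, a vesicle protein, and Id3 passed, with log2 differences of 0.95 and -1.64; both were named after their values were seen. For each of the 6 lists, adjusted p = 0.758 with an estimated correlation. Without the library labelled Ctrl_TTXwd replicate 3, none of them passed: the camera adjusted p was 0.0973 for GABA-A subunits, 0.398 for potassium channels, 0.975 for vesicle genes, 0.764 for cholesterol synthesis, 0.0773 for astrocyte markers and 0.98 for microglia markers. With median ratios the microglia list had 0.0541, and after quantile normalization the cholesterol list had 0.0506 and progenitor and cell cycle genes passed (0.0483). Without Ctrl_TTX replicate 1, the microglia and cholesterol lists each had 0.0833, and without KD_TTXwd replicate 2, 3 lists passed. Microglia marker means in log2 units were 5.08, 2.83 and 6.46 in Ctrl_TTXwd and 4.46, 2.06 and 4.84 in KD_TTXwd, and those of astrocytes 7.65, 6.90 and 7.62 against 6.92, 6.07 and 6.90. With the replicate block within treatment, an alternative chosen after the data were seen, limma called 90 genes. Among them, the astrocyte markers Gfap and Vim and the microglia marker C1qa were lower (limma adjusted p = 0.0337, 0.0425 and 0.0425). Whether replicate numbers pair these libraries is unclear, as same-numbered ones correlated at -0.331, 0.875 and 0.563.

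**Figure D3:**
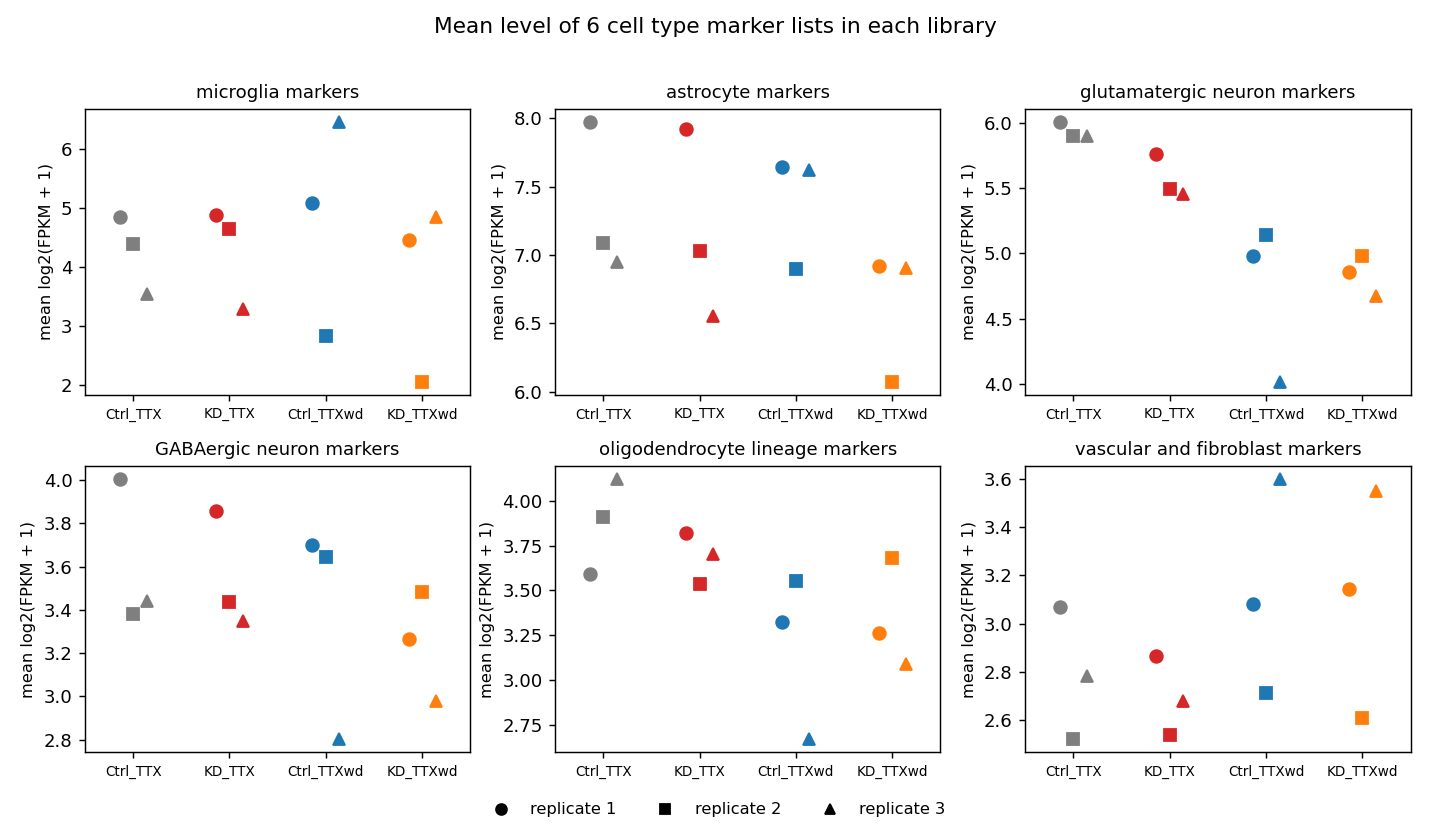
Mean log2(FPKM + 1) of the tested markers of 6 cell types in each of the 12 libraries. Each point is 1 library, by group.

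Whether withdrawal acted differently with knockdown was tested directly, as the difference between the 2 responses. By limma, 0 genes were higher and 0 lower (smallest adjusted p 0.492), with 1050 at an unadjusted p under 0.05 against 534 by chance; no other tool was run on this contrast. The 5 genes with the smallest p were Snapc2, a subunit of a small nuclear RNA transcription complex (log2 difference -1.18), Hivep2 (1.11), Prkaa2 (1.06), Prkx (1.05) and Ddit4l (-1.67). Arc had a difference of -1.07, with 1.25 and 3.33 FPKM in control and 2.18 and 1.72 FPKM with knockdown (limma adjusted p = 0.492). Homer1 had 0.73 (0.492), Bdnf 0.64 (0.566) and Fos -0.24 (0.865).

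As groups, 6 lists passed by camera for this difference. GABA-A receptor subunits had a median log2 change with withdrawal of -0.55 in control and 0.46 with knockdown (median difference 1.02, camera adjusted p = 0.000223), and cholesterol synthesis genes one of -0.38 and 0.48 (0.88, 0.00405). With knockdown the fall was smaller for potassium and HCN channels (-0.655 in control and -0.03 with knockdown; 0.48, 0.00362), glutamatergic neuron markers (-1.27 and -0.71; 0.43, 0.00528) and vesicle and release genes (-0.99 and -0.36; 0.57, 0.012). Interferon-stimulated genes had 0.50 in control and -0.09 with knockdown (-0.45, 0.012). Glial markers lay on the lower side of this difference: 11 of 12 astrocyte markers (median -0.42, 0.0708; 0.0456 after quantile normalization) and 14 of 14 microglia markers (-0.77, 0.0771; 0.0479). Quantile normalization also called the unfolded protein and integrated stress response (0.0456). With microglia and astrocyte marker means as covariates, an alternative chosen after the data were seen, interferon-stimulated genes had a camera adjusted p of 0.136 and cholesterol synthesis genes 0.141, and the other 4 of the 6 lists passed. For each of the 6, adjusted p = 0.768 with an estimated correlation. Without the library labelled Ctrl_TTXwd replicate 3, GABA-A subunits passed (0.0115), and the other 5 had camera adjusted p values from 0.229 to 0.748; 11 lists passed without KD_TTX replicate 1 and 10 without Ctrl_TTXwd replicate 2. By limma, 0 members passed over all genes. Among those that passed adjusted over the list alone were Bcl11b, a glutamatergic marker, and Grin2a of the NMDA list, with differences of 0.97 and 1.30, both named after their values were seen.

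Over all responding genes the difference was small and depended on single libraries. The 146 genes called higher by withdrawal, by at least 2-fold on average over the 2 genotypes, had a median difference of -0.22 (camera p = 0.00759; p = 0.324 with an estimated correlation). The median was -0.06 without KD_TTX replicate 3 and -0.09 without the library labelled Ctrl_TTXwd replicate 3, and camera over the 146 genes then gave p values of 0.192 and 0.203. The 570 genes called lower had a median difference of -0.15 (camera p = 0.0463; p = 0.735 with an estimated correlation). It turned to 0.01 without Ctrl_TTXwd replicate 2, and the camera p ran from 0.0721 to 0.869 without Ctrl_TTX replicate 1, 2 or 3, KD_TTX replicate 1, Ctrl_TTXwd replicate 1 or 2 or KD_TTXwd replicate 1. Across genes, the knockdown effects in TTX and after withdrawal correlated at r = -0.196 (rho = -0.224). This r was -0.0270 without Ctrl_TTX replicate 1, -0.0659 without KD_TTX replicate 1, -0.322 without KD_TTX replicate 3 and -0.104 without KD_TTXwd replicate 1, and 0.221 with the library labelled Ctrl_TTXwd replicate 3 and Ctrl_TTX replicate 1 both left out.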

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

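The tests of cell type shares and of neuronal transcripts in the library labelled Ctrl_TTXwd replicate 3, the count of its genes near control, the refit of the gene lists without it, the test of ribosomal protein genes and the exchange of genotype within replicate pairs were chosen only after the results were seen.

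The difference between the responses to withdrawal with knockdown and in control was itself tested. camera at a preset correlation of 0.01 called 6 gene lists for it: GABA-A receptor subunits (median difference 1.02), glutamatergic neuron markers (0.43), potassium and HCN channels (0.48), synaptic vesicle and release machinery (0.57), interferon-stimulated genes (-0.45) and cholesterol synthesis genes (0.88). It also called the genes higher after withdrawal (median -0.22) and the genes lower after withdrawal (-0.15). With an estimated correlation none of these passed: adjusted p = 0.768 for each list, and p = 0.324 and 0.735 for the genes higher and lower. Relabelled genotypes gave as many lists in 63 of 100 draws.

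In the library labelled Ctrl_TTXwd replicate 3, Grin3a stood at 4.88 FPKM, the level of knockdown libraries, against 13.8 and 19.8 FPKM in the other Ctrl_TTXwd libraries. A smaller share of neurons with every other cell type raised alike is argued against. Median differences ran from 2.56 for microglia to -0.69 for oligodendrocyte markers, a range of 3.25 log2 units. A smaller share of neurons with the other cell types raised unequally was not tested and stays open. Neuronal transcripts were low in this library, by medians of -0.87 for glutamatergic and -0.68 for GABAergic markers, a smaller fall than that of Grin3a (-1.58); 5 of 29 neuronal markers (17.2%) were as far below the other Ctrl_TTXwd libraries and 24 were not. Whether it is a mislabelled knockdown library cannot be told apart: over 200 genes that separate the other withdrawal libraries its median position between control (0) and knockdown (1) was 0.766, where knockdown libraries lay at 0.614 to 1.21 and the other controls at 0.097 and 0.462. Of these genes 15.5% lay near control, between the knockdown libraries (1% to 8%) and the other controls (74.5% and 23.5%), and 2 other controls are too few to give their spread. A control culture with less Grin3a stays open, untested.

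The 6 lists called for the difference had a median difference of 0.571 over their members, each taken in the direction of its list. A trend with locus span as the whole cause is argued against: after each library was corrected for it the median was 0.483, and all 6 lists had camera adjusted p values from 0.00173 to 0.023. Without the library labelled Ctrl_TTXwd replicate 3 the median was 0.388 and only GABA-A subunits passed, so the part of this library cannot be told apart with 3 libraries a group. The knockdown itself, which the design names, stays open.

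In both genotypes, 13 transcripts were lower after withdrawal by at least 2.5 log2 units, with every withdrawal library below every TTX library: Basp1, C1qtnf4, Cdk5r2, Eif3h, LOC652956, Nudc, Prr7, Rprml, Rps2, Scrt2, Sox12, Tmem158 and Zfp575. Their loci had a median span of 2108 bp, against 23798 bp over all genes tested, though Basp1 and Eif3h spanned 46826 and 84950 bp. An average trend with locus span as the cause is argued against: their median change over both genotypes was -3.41, and -3.25 after correction. Rps2 as part of a common fall of ribosomal protein genes is argued against as well, since 20 of 53 such genes were called higher in control neurons and 1 lower. Reads shared with pseudogenes, transcript length and GC content were not tested. Even with no new transcription after withdrawal, falls this large in 6 h need fast decay. In control neurons Rps2 RNA, 284-fold lower, would have to halve at least every 44.2 min. The bounds were 70.6 min for Tmem158, 76.3 min for Nudc and 99.4 min for Basp1. Decay of these RNAs was not measured. The withdrawal of TTX, which the design names, stays open.

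Other splits of the same libraries were counted for each model result. For each comparison of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real split called 0 genes for knockdown in TTX (all 10 splits called as many), 1896 for withdrawal in control (1 of 10), 1 for knockdown after withdrawal (1 of 10) and 1514 for withdrawal with knockdown (1 of 10), and the highest other split called 0 in each. The real splits called 1, 12, 6 and 2 gene lists, and the highest other splits 7, 15, 17 and 13, with 9, 5, 9 and 9 of the 10 splits calling as many. Replicate numbers appear to pair the libraries in TTX. Of the splits that part every pair, the 3 other than the real one called 0, 1 and 4 lists. The 6 that keep a pair together called 1 to 7. For the difference between the responses, genotype was relabelled within each treatment, giving 100 draws. The count of genes decides nothing there, since the real count is 0 and all 100 draws call as many (highest other 2). Chance could not be excluded for the gene lists (6 and 18, as large in 63), for the median of genes higher after withdrawal (-0.22 and 0.53 in size, as large in 35) or lower after it (-0.15 and 0.85, as large in 76), or for the correlation of the knockdown effects (-0.196 and 0.569, as large in 60). These draws do not keep the pairs. With genotype exchanged only within same-numbered libraries of a treatment, in 32 labellings, chance could not be excluded either. As many lists were called in 13 (real 6, highest other 16), and in 11 with the replicate block within treatment (real 11, highest other 17). Medians were as large in 12 for genes higher and 26 for genes lower (highest others 0.45 and 0.80 in size), and the correlation in 30 (highest other 0.569).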

How the results depend on the processing

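The alternatives with a replicate block within treatment, with both outlying control libraries left out (Ctrl_TTX replicate 1 and the library labelled Ctrl_TTXwd replicate 3), with microglia and astrocyte marker means as covariates, with library weights and with each library corrected for locus span were chosen after seeing the data; the error rate of the weights, which ran from 0.102 to 9.38, was not tested. Of the 141 calls of named genes in a comparison, none changed direction under any alternative. These calls were chosen as past the threshold, and those with the largest changes also for groups that do not overlap. Leaving out libraries could not turn the direction of the latter. Of the 141 calls, 0 were lost with a pseudocount of 0.1, 11 with the correction for locus span and 73 with only the 6 libraries compared. Without replicate 3, 88 were lost, and without replicate 2, 141. Where 1 replicate is left out of a group of 3, the spread is pooled over groups. A 6-library fit does not exist for the difference between responses. Read depth, which limits the precision of low values, is unknown. For each change below without a stated reason, the cause was not tested.

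For genes, the weights called 619 higher and 1012 lower for knockdown in TTX, 2128 and 2851 for withdrawal in control, 960 and 1338 for knockdown after withdrawal, 2366 and 2821 for withdrawal with knockdown, and 829 and 899 for the difference between responses. The covariates called 1717 and 1978 for withdrawal in control, 383 and 405 for knockdown after withdrawal, and 1482 and 2022 for withdrawal with knockdown. Without both outlying libraries, 124 and 403 were called for knockdown after withdrawal and 1452 and 2079 for withdrawal with knockdown. With only the 6 libraries compared, the counts were 1 and 0 for withdrawal in control, 0 lower for knockdown after withdrawal, and 921 and 1601 for withdrawal with knockdown. Quantile normalization called 0 lower for knockdown after withdrawal and 947 higher for withdrawal with knockdown, and the correction for locus span 0 lower and 949 higher. With single libraries or replicate numbers left out, higher genes ran from 0 to 742 and lower from 0 to 1287 for withdrawal in control, lower from 0 to 4 for knockdown after withdrawal, and higher from 0 to 1025 and lower from 0 to 1609 for withdrawal with knockdown.

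With a replicate block over 12 libraries, knockdown in TTX called 0 genes, knockdown after withdrawal 0 lower, withdrawal in control 817 higher and 1252 lower, and withdrawal with knockdown 553 and 1014. The block within treatment called 1215 higher genes for withdrawal in control, and 33 higher and 57 lower for knockdown after withdrawal. The numbers of gene lists called were 4 and 3 for knockdown in TTX with the block over 12 libraries and within treatment, 4 for withdrawal with knockdown within treatment, and 11 for the difference between responses with either block. For knockdown in TTX, where the numbers appear to pair the libraries, the block changed no call of a single gene and no list other than those named in the results. Elsewhere they share only a number: same-numbered libraries deviated together at -0.331, 0.875 and 0.563 for knockdown after withdrawal, -0.301, 0.0673 and -0.497 for withdrawal in control, and 0.314, -0.179 and -0.448 for withdrawal with knockdown.

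For the median difference between responses, genes higher after withdrawal (-0.22) ran from -0.50 to 0.0037 with libraries left out, and turned to 0.0037 without replicate 3 and to 0.10 with the covariates; the median was -0.051 without both outlying libraries, -0.12 with the weights and -0.10 with the correction for locus span, no longer past the threshold. Genes lower after withdrawal (-0.15) ran from -0.51 to 0.22, turned to 0.01 without Ctrl_TTXwd replicate 2, 0.22 without replicate 1, 0.04 without replicate 2 and 0.19 with the block within treatment, and were no longer past the threshold at -0.20 with median ratios and -0.16 with the block over 12 libraries. The correlation of the knockdown effects ran from -0.372 to 0.0759 with libraries left out (0.0759 without replicate 1), and turned to 0.221 without both outlying libraries and 0.0505 with the weights; it was -0.116 with the correction for locus span.

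Of the gene lists, an estimated correlation called 0 in each comparison, and fry called 0 for both knockdown comparisons and the difference between responses, 12 for withdrawal in control and 2 for withdrawal with knockdown. Of the 12, 11 were also called by camera; of the 2, none was. For knockdown in TTX (1 list), median ratios, quantile normalization and the correction for locus span called 2 each, the covariates 3, leaving out both outlying libraries 5 and the weights 8. For withdrawal in control (12), leaving out both outlying libraries called 6 and the correction for locus span 7. For knockdown after withdrawal (6), leaving out both called 0 and the weights 2. For withdrawal with knockdown (2), a mean FPKM of at least 5 and the weights called 1 each, and the correction for locus span 4. With libraries left out, the counts ran from 1 to 6, from 5 to 16, from 0 to 11, from 1 to 5 and, for the difference between responses (6), from 1 to 12.

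Of the genes in the authors' deposited lists, those called here for withdrawal in control (1463) numbered 1 with only the 6 libraries compared and 0 to 1486 with libraries left out. Those for withdrawal with knockdown (1223) numbered 687 with the block within treatment, 1880 without both outlying libraries, 1983 with the weights and 0 to 1643 with libraries left out. Those for knockdown after withdrawal (1) numbered 0 with quantile normalization, the correction for locus span, the block over 12 libraries or only the 6 libraries compared, 84 with the block within treatment, 224 without both outlying libraries, 214 with the covariates, 508 with the weights and 0 to 4 with libraries left out. Those for knockdown in TTX (0) numbered 125 with the weights.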

Other observations

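Beyond the lists fixed in advance, genes of the antioxidant response were looked at after their values were seen. Gclc, the catalytic subunit of glutathione synthesis, rose with withdrawal from 37.1 ± 14.5 to 80.4 ± 35.4 FPKM in control (limma adjusted p = 0.0344) and from 36.0 ± 3.34 to 77.4 ± 15.3 FPKM with knockdown (0.0391). Gsta1 rose with knockdown too, from 15.2 ± 2.88 to 55.5 ± 27.0 FPKM (0.0283). Srxn1, which rose in control (0.00327), did not pass with knockdown (log2 change 0.83, 0.104). Hmox1, the heme oxygenase, stood at 41.3 ± 11.5 FPKM in Ctrl_TTX, 62.3 ± 15.4 in KD_TTX, 113 ± 73.3 in Ctrl_TTXwd and 48.6 ± 25.3 FPKM in KD_TTXwd, and passed in no comparison (limma adjusted p from 0.0727 to 0.936). Gclm, Txnrd1 and Slc7a11 passed in no comparison.

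Of 53 ribosomal protein genes, 20 were higher and 1 was lower after withdrawal in control, with a median log2 change of 0.63, and 14 were higher and 3 lower with knockdown, with a median of 0.45. Their changes had SDs of 1.34 and 1.47, and without Rps2 of 0.91 and 1.01. This was wider than the 0.63 and 0.61 of all genes with a mean FPKM above a cut near their low end. That set was not matched in abundance to the ribosomal protein genes, whose median was 127 FPKM.

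The change of a gene went with the span of its locus. Across genes, Spearman's rho between span and log2 change was -0.319 for knockdown in TTX, -0.214 for withdrawal in control, 0.288 for knockdown after withdrawal, 0.101 for withdrawal with knockdown and 0.381 for the difference between responses. In control neurons, withdrawal left 96 genes higher and 490 lower among the 2672 genes with the longest loci (median 118 kb), and 255 higher and 198 lower among the 2673 with the shortest (4.85 kb).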
